A study of Mus musculus with 74 samples.

How the data were processed

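RNA was sequenced from spinal cord microglia (MG) and from sciatic nerve macrophages (MP) of female mice, both taken with magnetic beads against CD11b, a surface marker of myeloid cells. Neutrophils and monocytes also carry CD11b, so the bead step does not remove them. The disease model is the mutant human SOD1-G93A transgenic mouse, a model of amyotrophic lateral sclerosis. It was sampled before symptoms, at onset, in early symptoms and at end stage. Controls were mice with a wildtype human SOD1 transgene (WT below) and non-transgenic C57BL/6J mice (B6 below), each at an age near onset and an age near end stage. A further set of G93A mice received bone marrow at onset from a G93A or a WT donor and was sampled in early symptoms or at end stage. Per the labels' protocols, an MG library came from 1 spinal cord and an MP library from the sciatic nerves of 1 mouse, except that pre-symptomatic MP libraries pooled the nerves of 2 mice.

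Groups came from the labels, which put 74 libraries in 21 groups. The 51 non-grafted libraries are 33 MG and 18 MP, and the 23 grafted libraries are 12 MG and 11 MP. The labels conflict for 4 MP libraries at the age of end stage. Their descriptions say WT, while title, source and strain say G93A. They were grouped by the description and are called "described as WT" throughout.

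The authors deposited 2 tables of FPKM (fragments per unit of transcript length and of mapped fragments), 1 for the non-grafted and 1 for the grafted libraries, per the file headers. The values are written with decimal commas and 2 decimals. The submitters' processing notes name FastQC, Picard, SAMtools, DESeq2, R 3.2.5 and the mouse build mm10, with no role for each. The aligner, the counting step and whether it used strand are not given in the sources used here. Each table holds 58976 features, of which 23297 carry a gene symbol and 35679 do not. Of 22225 symbols that a GENCODE vM21 annotation also holds, 22178 (99.8%) overlap the same locus there. A spreadsheet had turned 27 symbols of the non-grafted table into dates, and 361 features carry several symbols. Features without a symbol held between 9.87% and 29.33% of a non-grafted MG library's FPKM. They were left out of the tests. FPKM sums ran from 484604 to 618562 in non-grafted MG, 625386 to 986659 in non-grafted MP, 483480 to 572765 in grafted MG and 615421 to 755253 in grafted MP. Read depth is unknown, so no counting interval can be given. The number of genes above 1 FPKM ran from 10127 to 11697 per non-grafted MG library and from 7939 to 10031 per non-grafted MP library. No 2 libraries were identical, and the highest correlation between any pair was 0.9955 in the non-grafted and 0.9933 in the grafted table.

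FPKM are not counts, so differences were tested with limma 3.58.1 in R 4.3.3 (lmFit on group means, then eBayes with a mean-variance trend) on log2(FPKM + 1). A gene was tested if its mean was at least 1 FPKM over the libraries of the fit, and called at a Benjamini-Hochberg adjusted p under 0.05. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Errors of fold changes are SE and errors of FPKM are SD. Separate fits held the 33 non-grafted MG, the 18 non-grafted MP, the 12 grafted MG and the 11 grafted MP libraries. The difference between MP and MG in the change from pre-symptomatic to end stage was tested in 1 fit of all 51 non-grafted libraries. Grafted and non-grafted libraries were never tested against each other, because each table may have been scaled on its own. Replicates are separate mice or pools of mice.

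Before the data were examined, 34 gene lists were fixed, 13 of them markers of cell types other than microglia. The text reports those for homeostatic and disease-associated microglia, type I interferon response, inflammatory cytokines and NF-kB targets, MHC class I and class II presentation, complement and Fc receptors, lysosome, oxidative phosphorylation, cholesterol synthesis, lipid efflux and storage, cell cycle, trophic factors, antioxidant response, NADPH oxidase and reactive oxygen, and alternative activation, and the markers of neutrophils, monocytes, bone-marrow-derived and border macrophages, astrocytes, oligodendrocytes, neurons and Schwann cells. Each list was tested with limma's camera, which compares its genes with all others, at a preset correlation between genes of 0.01 and again with an estimated correlation. Both were adjusted over the lists of a comparison. limma's fry asked whether a list's genes move, on balance, one way. A library's list score is the mean of log2(FPKM + 1) over the list, and score differences were tested with an exact two-sided permutation test.

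The rule for named genes was also set before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes with at least 5 FPKM in the higher group and no overlap between the groups' libraries. It adds up to 4 called members of each list and, in every comparison, Sod1 and a set of key microglial genes. Where fewer than 5 genes pass, it adds the 5 with the smallest p, given as not passing. The text names a part of that selection. MHC class I genes such as H2-D1 have close paralogs that share sequence, so their values are uncertain. A feature without a symbol lies opposite Apoe, and without a stated strand the reads of both cannot be told apart. The mouse Sod1 row does not measure the human transgene.

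The alternatives planned beforehand were a pseudocount of 0.1, no filter, median-ratio scaling, only the groups compared, the replicate number as a block, limma's library quality weights, leaving out each replicate, B6 in place of WT controls, and for MP a term for libraries numbered 100 and above in their descriptions. Terms for the cell marker scores of each library and the removal of MG libraries with S100a8 above 10000 FPKM were added after seeing the data, as was a term for MP library numbers in the fit of the difference between MP and MG. A removal of MG libraries with little Mbp was also tried and withdrawn, since Mbp differs with disease stage. The oligodendrocyte score differs with stage too, so terms for it also take up effects of stage. Other splits of the same libraries, at most 100 per comparison, were counted to see how often as many genes are called.

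The fits were first tested on simulated data with the real group sizes and the real spread of each gene. Each gene was drawn on its own, so variation that genes of a library share was left out. The rates below therefore need not hold for the real libraries. For end-stage against WT microglia, 49 of 100 genes changed by 1 log2 unit and 86 of 100 changed by 2 were called, with 5 of 11550 unchanged genes. For MP at end stage against pre-symptomatic, 1 of 100 and 27 of 100 were called. For grafted MG at end stage it was 14 of 100 and 70 of 100, and for grafted MP at end stage 0 of 100 and 8 of 100. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.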

Results

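RNA was sequenced from CD11b-selected spinal cord microglia (MG) and sciatic nerve macrophages (MP) of female mice, in 74 libraries and 21 groups. Non-grafted MG came from SOD1-G93A mice before symptoms (n = 4, mean age 50.8 days), at onset (n = 5, 105 days), in early symptoms (n = 4, 152.6 days) and at end stage (n = 4, 169.4 days). Their controls were WT mice, which carry wildtype human SOD1, at the age of onset (n = 4, 107.3 days) and of end stage (n = 4, 165.4 days), and non-transgenic B6 mice at the same stages (n = 4 each, 109.8 and 165.6 days). Non-grafted MP came from G93A mice before symptoms (n = 3), at onset (n = 3), in early symptoms (n = 4) and at end stage (n = 4), and from 4 mice at the age of end stage that are described as WT but carry a G93A strain label. Grafted G93A mice had bone marrow from a G93A or a WT donor, with 3 mice per donor, stage and cell type, except 2 for MP with WT marrow in early symptoms. Values are FPKM, and read depth is not given in the sources used here. FPKM sums per library ran from 484604 to 618562 in non-grafted MG and from 625386 to 986659 in non-grafted MP. Transcripts of other cells were present throughout. S100a8, a neutrophil gene, was at 8355 to 80760 FPKM in non-grafted MP libraries, and Hba-a1, a hemoglobin gene, at 2479 to 115143 FPKM. Mbp, a myelin gene of oligodendrocytes, was at 21094 to 24164 FPKM in pre-symptomatic MG. Positions below are on mm10.

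The comparison of end-stage G93A with WT microglia of the same age asked how mutant SOD1 disease changes microglia beyond the presence of a human SOD1 transgene. Gpnmb (chromosome 6, 49036518 to 49070929), which encodes a glycoprotein of lysosome-rich phagocytes, was higher by 6.08 ± 0.92 (log2, SE; adjusted p = 0.000193), at 1390 ± 720 against 25.5 ± 16.3 FPKM (SD, n = 4 each). Apoe (chromosome 7, 19696109 to 19699188), the lipid carrier of disease-associated microglia, was higher by 2.95 ± 0.52 (adjusted p = 0.000915), at 25500 ± 8710 against 3130 ± 505 FPKM. Igf1, a growth factor, rose by 3.75 ± 0.55 from 1.27 ± 0.82 FPKM, and Spp1 (chromosome 5, 104435111 to 104441053), which encodes the matrix protein osteopontin, rose by 3.73 ± 0.92 to 6500 ± 3050 FPKM. P2ry12 (chromosome 3, 59216271 to 59262985), the purinergic receptor of resting microglia, fell by 2.35 ± 0.64 (adjusted p = 0.0238), from 1270 ± 389 to 257 ± 102 FPKM.

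Other large rises in that comparison were Atp6v0d2, a subunit of the lysosomal proton pump (4.82 ± 0.60), Colec12, a scavenger receptor (4.26 ± 0.56), Hspb1, a small heat shock protein (4.25 ± 0.76), Cst7, a cathepsin inhibitor (4.23 ± 0.82), and Ms4a7, a membrane gene of macrophages (4.08 ± 0.72). Among genes of lipid handling, Apoc1 rose by 2.82 ± 0.41 and Lpl, which encodes lipoprotein lipase, by 2.29. Hmox1, which encodes a heme-degrading enzyme, rose by 2.15 ± 0.46, and the complement gene C4b by 1.67. The falls included Slc2a5, which encodes a fructose transporter of microglia (-2.45 ± 0.64), and Crybb1 (-1.92), a crystallin gene of microglia. They also included the cholesterol synthesis genes Idi1 (-2.04) and Sqle (-1.96 ± 0.39). The astrocyte genes Slc7a10 (-3.78 ± 0.87) and Bcan (-3.63) fell furthest. The microglial genes Tmem119 (-1.73, adjusted p = 0.0966) and Cx3cr1 (-0.60, adjusted p = 0.58) and the lectin gene Clec7a (2.36, adjusted p = 0.0534) did not pass. Mouse Sod1 did not either (-0.15, adjusted p = 0.758).

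Of the 25 measured disease-associated genes, 12 were higher and 0 lower at end stage than in WT, or 17 and 0 adjusted over the list alone. The median change was 1.95 (camera adjusted p = 8.62e-21), with adjusted p = 0.12 with an estimated correlation. Of 15 lipid efflux and storage genes 8 were higher (10 adjusted over the list alone; median 1.51, camera adjusted p = 1.35e-11; adjusted p = 0.11 with an estimated correlation). Of 16 cholesterol synthesis genes 9 were lower (14 adjusted over the list alone; median -1.15, camera adjusted p = 8.98e-09; adjusted p = 0.159 with an estimated correlation). Of 20 homeostatic genes 3 were lower (5 adjusted over the list alone; median -0.95, camera adjusted p = 0.0155; adjusted p = 0.677 with an estimated correlation). The lysosome list had 1 higher gene of 21 (3 adjusted over the list alone; median 0.79, camera adjusted p = 3.69e-08; adjusted p = 0.535 with an estimated correlation). For the interferon list (median 0.41, camera adjusted p = 0.00266) and oxidative phosphorylation (median -0.44, camera adjusted p = 0.00853) no gene passed, and for both the result was adjusted p = 0.677 with an estimated correlation. Mitochondrial genes held 2.09% to 4.91% of FPKM at end stage and 3.41% to 10.77% in WT. For MHC class II the median was 0.01 and the mean -0.04 (camera adjusted p = 0.553). The astrocyte markers had a median of -1.91 (1 of 9 lower; camera adjusted p = 0.038; adjusted p = 0.677 with an estimated correlation), the oligodendrocyte markers -0.82 (camera adjusted p = 0.135) and the neuronal markers -0.98 (camera adjusted p = 0.113). The neutrophil markers had a median of -1.86 (camera adjusted p = 0.242) and the monocyte markers -1.21 (camera adjusted p = 0.424). The markers of bone-marrow-derived and border macrophages had a median of -0.07 and a mean of 0.36, with 1 of 8 higher (camera adjusted p = 0.104).

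In total 822 of 11750 genes differed between end-stage G93A and WT microglia, 330 higher and 492 lower, with 196 and 186 of these at least 2-fold. With median-ratio scaling the split was 537 higher and 255 lower. The count was 379 with only the groups compared, 2209 with terms for oligodendrocyte and neutrophil scores and 1669 without the libraries with S100a8 above 10000 FPKM. It was 5432 with B6 in place of WT controls and 5714 with library quality weights, which ran from 0.0643 to 11.5. It was 357, 480 or 426 without G93A end-stage replicate 1, 2 or 3, and 373 or 524 without WT replicate 3 or 4.

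The stage comparisons asked how the profile of G93A microglia develops as disease advances. Age rises with stage from 50.8 to 169.4 days, so stage and age cannot be separated in these contrasts. From the pre-symptomatic to the end stage, Gpnmb rose by 8.53 ± 0.92 (adjusted p = 1.17e-06), from 3.22 ± 3.32 to 1390 ± 720 FPKM (SD, n = 4 each). Spp1 rose by 8.27 ± 0.92 (adjusted p = 1.68e-06), Cst7 by 7.64 ± 0.82 and the galectin gene Lgals3 by 6.40. Cybb, the catalytic subunit gene of the phagocyte NADPH oxidase, rose by 5.49, and Clec7a by 5.24. The integrin gene Itgax rose by 4.86, Igf1 by 4.54 ± 0.55 and Apoe by 3.25 ± 0.52. Antigen presentation and lysosome genes rose as well, among them Cd74 by 3.69, Cd68 by 3.67 and Ctsd by 3.73. The homeostatic genes P2ry12 (-0.83, adjusted p = 0.263), Tmem119 (-0.11) and Cx3cr1 (0.46) did not pass against the pre-symptomatic group, and neither did Sod1 (-0.36, adjusted p = 0.236).

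By end stage 24 of 25 disease-associated genes were higher than before symptoms (median 3.67, camera adjusted p = 3.6e-15; adjusted p = 0.324 with an estimated correlation). The lysosome list was higher in all 21 measured genes (median 2.55), the interferon list in 21 of 22 (median 1.66), MHC class I in 12 (median 2.02) and the cell cycle list in all 20 (median 2.19). Complement and Fc receptors were higher in 14 of 16 genes (median 2.70), and the proliferation gene Birc5 rose by 3.53. Cholesterol synthesis was lower in 15 of 16 genes (median -1.55), with Idi1 at -3.05. Oxidative phosphorylation was lower in 18 of 22 genes and higher in 1 (median -0.85), while the share of FPKM from mitochondrial genes was 6.86% to 13.41% per library before symptoms and 2.09% to 4.91% at end stage. None of these lists passed with an estimated correlation, where the adjusted p was 0.324 to 0.401. The astrocyte markers fell in 8 of 9 genes (median -3.13; adjusted p = 0.357 with an estimated correlation), oligodendrocyte markers in 9 of 10 (adjusted p = 0.401 with an estimated correlation) and neuronal markers in 7 of 9 (median -2.12; adjusted p = 0.357 with an estimated correlation). The glutamate transporter gene Slc1a2 of astrocytes fell by 4.23 and Mbp by 2.65, from 22800 ± 1320 to 4400 ± 2920 FPKM (SD, n = 4 each). Neutrophil markers rose in 6 genes (median 3.84; adjusted p = 0.459 with an estimated correlation), with S100a8 at 5430 ± 9990 FPKM and one library, end-stage replicate 4, at 20413 FPKM. In all, 2914 genes were higher and 3657 lower, 6571 of 11750, with 1603 and 2231 of these at least 2-fold. With terms for oligodendrocyte and neutrophil scores 2269 genes were called, of which 1741 were among the 6571, 6 of them in the opposite direction. The oligodendrocyte score itself was 7.088 to 7.483 before symptoms and 4.383 to 6.415 at end stage, so these terms also take up effects of stage. Against WT of the same age the cell cycle list was not stable. Its median was -0.056 without WT replicate 3, 0.704 without WT replicate 1 and -0.372 with library quality weights.

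Early-symptom microglia were set against the same pre-symptomatic group. Spp1 was higher than before symptoms by 7.97 ± 0.92 (adjusted p = 8.41e-06), at 4740 ± 840 against 29.9 ± 37.6 FPKM (SD, n = 4 each), Gpnmb by 7.25 ± 0.92 and Cst7 by 7.19 ± 0.82. Apoe was higher by 2.79 ± 0.52, at 17700 ± 3120 FPKM. Trem2, a lipid-sensing receptor gene, rose by 2.65, and the interferon response genes Ifit3 and Irf7 by 2.07 and 2.13. P2ry12 did not change past the threshold (-0.07, adjusted p = 0.932). All 22 interferon genes and 24 of 25 disease-associated genes were higher (medians 1.95 and 3.54; camera adjusted p = 4.44e-11 and 1.4e-18; adjusted p = 0.309 with an estimated correlation for both), and 13 of 16 cholesterol synthesis genes were lower (median -1.12; adjusted p = 0.309 with an estimated correlation). Astrocyte markers were lower in 5 of 9 genes (median -1.92; adjusted p = 0.439 with an estimated correlation). The oligodendrocyte gene Mobp fell by 2.21 and the neuronal gene Nefl by 2.24, and mitochondrial genes held 2.09% to 8.92% of FPKM against 6.86% to 13.41% before symptoms. In limma 2256 genes were higher and 1881 lower, 4137 in total, and 2478 with terms for oligodendrocyte and neutrophil scores, 2194 of them shared, and 8357 with library quality weights. The count was 2294 or 2113 without pre-symptomatic replicate 1 or 2, and 1534 without early-symptom replicate 2.

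At onset the comparison with WT mice of the same age asked which changes are present as symptoms begin. Spp1 was higher by 4.70 ± 0.87 (adjusted p = 0.0163), at 1500 ± 2360 (SD, n = 5) against 19.9 ± 5.51 FPKM (SD, n = 4). The matrix protease gene Mmp12 was higher by 3.88 ± 0.79, Cst7 by 3.64 ± 0.78, and Ch25h, which makes 25-hydroxycholesterol, by 3.61 ± 0.71. Lgals3 rose by 3.36 ± 0.84 and Clec7a by 2.89 ± 0.71. The chemokine genes Ccl3 and Ccl4, close paralogs, rose by 3.02 and 2.82, Igf1 by 1.79 and the cell division genes Ccnb2 and Top2a by 2.32 and 1.76. Sod1 (chromosome 16, 90220742 to 90226331), the mouse gene, was lower by 0.93 ± 0.25 (adjusted p = 0.0482), at 29.6 ± 15.2 against 52.4 ± 7.95 FPKM. Falls also included the oligodendrocyte gene Mog (-1.87), Insig1 (-1.52) and Fdft1 (-1.36) of the cholesterol synthesis list and the respiratory chain genes Uqcrh (-1.23) and Cox6c (-1.18). Apoe (0.86, adjusted p = 0.208), P2ry12 (-0.21, adjusted p = 0.804) and Cybb (2.66, adjusted p = 0.053) did not pass. The calls of this contrast are not stable. Of all genes tested, 0 passed with only the groups compared, 4 with the replicate number as a block and 2 to 5 when any 1 WT library was left out.

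Among gene groups at onset, 11 of 25 disease-associated genes were higher than in WT (16 adjusted over the list alone; median 1.79, camera adjusted p = 3.24e-11; adjusted p = 0.455 with an estimated correlation). The same adjusted p = 0.455 with an estimated correlation held for the cell cycle list, with 8 of 20 genes higher and 19 adjusted over the list alone. It also held for oxidative phosphorylation, with 13 of 22 lower and 21 adjusted over the list alone (median -0.81). The homeostatic list had a median of 0.07 (camera adjusted p = 0.706). Astrocyte, oligodendrocyte and neuronal markers were lower, with medians of -2.25, -1.88 and -1.82 and camera adjusted p = 0.000409, 0.000176 and 0.000129. Of these markers 8, 10 and 9 passed when adjusted over the list alone, with adjusted p = 0.455 with an estimated correlation for all 3 lists. The onset libraries were split in their myelin RNA, with Mbp at 23950 and 18996 FPKM in replicates 1 and 4 against 1575 and 2194 FPKM in replicates 2 and 5 and a still lower value in replicate 3. Replicate 5 also had S100a8 at 39129 FPKM. The share of FPKM from mitochondrial genes ran from 0.74% to 11.68% across the onset libraries.

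The onset contrast called 506 of 11750 genes, of which 384 were lower, and 29 higher and 4 lower with median-ratio scaling. The count rested on every library, and it was 0 with only the groups compared, 4 with the replicate number as a block and 6 with terms for oligodendrocyte and neutrophil scores. With library quality weights it was 7935, and with B6 in place of WT controls 6477. It was 4978 or 4250 without onset replicate 1 or 4, and 5, 5 or 16 without onset replicate 2, 3 or 5. Without WT replicate 1, 2, 3 or 4 it was 5, 4, 2 or 4. Against the pre-symptomatic group the onset group had 2982 differing genes, 1216 higher and 1766 lower, but 8934 with library quality weights, 0 with only the groups compared, 0 with the replicate number as a block and 1 with terms for oligodendrocyte and neutrophil scores. Spp1 rose by 4.82 ± 0.87, Cst7 by 4.11 and Clec7a by 3.24, and Sod1 fell by 0.69 (adjusted p = 0.044), a change of 0.011 once terms for oligodendrocyte and neutrophil scores were fitted. Of the list genes 20 of the 25 disease-associated and 18 of the 22 interferon genes were higher (interferon median 1.41; adjusted p = 0.376 with an estimated correlation for both). In that contrast the astrocyte markers had a median of -2.45 with 8 genes lower (adjusted p = 0.376 with an estimated correlation), and Mbp fell by 2.55 ± 0.78, to 9460 ± 11100 FPKM (SD, n = 5). The count was 10, 0 or 0 without pre-symptomatic replicate 1, 2 or 3, 6968 or 6483 without onset replicate 1 or 4, and 0, 0 or 6 without onset replicate 2, 3 or 5.

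A score of disease-associated minus homeostatic genes gave 1 value per mouse. It was 2.03 ± 0.22 at end stage and -1.07 ± 0.40 in age-matched WT mice (SD, n = 4 each), a difference of 3.09 (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allow). At onset it was -0.19 ± 0.88 against -2.05 ± 0.25 in WT (difference 1.86, exact permutation p = 0.00794). Before symptoms it was -1.75 ± 0.90, lower than in early symptoms by 3.25 and than at end stage by 3.78 (exact permutation p = 0.0286 each). The onset and pre-symptomatic values overlapped and differed by 1.56 (exact permutation p = 0.0317). After adjustment of the exact permutation tests over 7 such comparisons these 5 had p = 0.0444. WT and B6 mice differed by 0.57 at the age of end stage and by -0.48 at the age of onset (exact permutation p = 0.114 each), and B6 microglia were at -1.64 ± 0.23 and -1.58 ± 0.40.

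**Figure D1:**
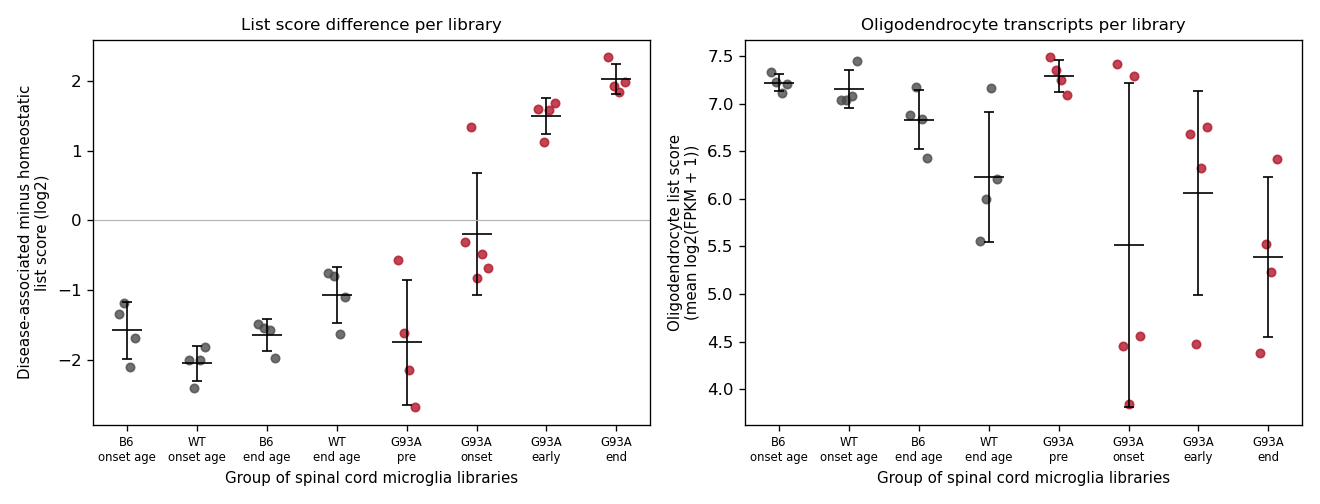
Scores of gene lists in each non-grafted microglia library, in log2(FPKM + 1) units, for the 8 groups, with G93A in red and controls in grey. The left panel shows the disease-associated minus the homeostatic score and the right panel the score of oligodendrocyte markers; points are libraries and bars are the mean ± SD. On the left, end-stage G93A is at 2.03 ± 0.22 and WT of that age at -1.07 ± 0.40.

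WT and B6 microglia were compared to ask whether the wildtype human transgene by itself changes microglia. At the age of onset 0 of 11750 genes passed in limma, with 727 at unadjusted p under 0.05. P2ry12 (1.61 ± 0.64, adjusted p = 0.759), Tmem119 (1.62) and Cx3cr1 (1.49) did not pass. The genes with the smallest p, also not passing, were Atg4c (0.49), Mnt (0.54), Smad3 (0.60), Ufl1 (0.60) and Anapc1 (0.68). Of the homeostatic genes 15 passed, all higher in WT, when adjusted over the list alone (median 1.47, camera adjusted p = 1.48e-10; adjusted p = 0.64 with an estimated correlation). At the age of onset the neutrophil score was 2.736 to 4.839 in WT against 1.307 to 3.088 in B6. The oligodendrocyte score was 7.032 to 7.444 against 7.11 to 7.334, and mitochondrial genes held 8.05% to 11.58% of FPKM against 10.45% to 13.77%. At the age of end stage 0 genes passed in limma, with 2421 at unadjusted p under 0.05. Spp1 (3.47 ± 0.92, adjusted p = 0.238), at 589 ± 354 in WT against 45.3 ± 28.7 FPKM in B6 (SD, n = 4 each), and Mmp12 (3.76 ± 0.84) did not pass. Adjusted over the list alone, 12 disease-associated genes were higher in WT (median 1.48, camera adjusted p = 1.33e-06; adjusted p = 0.393 with an estimated correlation). Of the 20 cell cycle genes 16 were higher (median 1.44, camera adjusted p = 3.03e-08; adjusted p = 0.393 with an estimated correlation). So were 12 neutrophil markers (median 3.64, camera adjusted p = 9.29e-05; adjusted p = 0.393 with an estimated correlation), with S100a8 at 32464 and 16679 FPKM in WT replicates 1 and 2. Mitochondrial genes held 3.41% to 10.77% of FPKM in WT against 7.8% to 14.29% in B6, and the oligodendrocyte score was 5.553 to 7.164 against 6.431 to 7.178. Without WT replicate 3, 10 genes passed. With library quality weights 8820 genes were called, and 4242 at the age of onset. The effect of age on the difference between WT and B6, tested as an interaction, had 0 genes in limma (242 at unadjusted p under 0.05).

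For sciatic nerve macrophages the stage comparisons asked whether peripheral macrophages change along with disease. From the pre-symptomatic (n = 3) to the end stage (n = 4), 1 of 10260 genes passed in limma, with 671 at unadjusted p under 0.05. This was Il1r2 (chromosome 1, 40084714 to 40125230), the decoy receptor gene for interleukin-1, higher by 1.87 ± 0.27 (adjusted p = 0.0108), at 425 ± 238 against 105 ± 7.41 FPKM. It did not pass without pre-symptomatic replicate 2 (adjusted p = 0.0711) and in 3 other settings. The adjusted p was 0.86 with only the groups compared, 0.535 with a term for library numbers and 0.0544 with the replicate number as a block. Mgl2, a lectin gene of tissue macrophages, was at 4.6 ± 1.83 against 244 ± 290 FPKM and did not pass (-4.44 ± 0.79, adjusted p = 0.0871). Spp1 (0.36 ± 1.16, adjusted p = 0.969), Apoe (0.06 ± 0.72, adjusted p = 0.994) and Igf1 (-1.04) did not pass. Of 21 interferon genes 0 passed over all genes and 7 were lower adjusted over the list alone (median -1.04, camera adjusted p = 3.01e-10; adjusted p = 0.323 with an estimated correlation), among them Ifit3 with a change of -2.29 that did not pass over all genes (adjusted p = 0.547). The Schwann cell markers had a median of -2.21 (camera adjusted p = 0.00176; adjusted p = 0.809 with an estimated correlation), and the disease-associated list 0.16 (camera adjusted p = 0.0919). All 3 pre-symptomatic libraries are numbered 100 and above and all early-symptom and end-stage ones below, so numbering and stage cannot be told apart in these contrasts. A term for library numbers rests on the onset group and the group described as WT, which hold both kinds. The end-stage count was 61, 0 or 2 without pre-symptomatic replicate 1, 2 or 3.

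At onset and in early symptoms 0 MP genes passed in limma against the pre-symptomatic group, with 474 and 535 at unadjusted p under 0.05. The genes with the smallest p at onset included Ctsf, a cathepsin gene (-3.67), and Epc1, a chromatin gene (-2.61), and in early symptoms Olfm4, a neutrophil granule gene (2.92, adjusted p = 0.499), and Cbr2 (-3.91), none of them passing. In early symptoms the disease-associated list had a median of 0.29 (camera adjusted p = 0.00582; adjusted p = 0.798 with an estimated correlation), and -0.052 with a term for library numbers. Cholesterol synthesis had a median of -0.67 (camera adjusted p = 0.0049; adjusted p = 0.784 with an estimated correlation) and the neutrophil markers 0.21 (camera adjusted p = 0.0385; adjusted p = 0.798 with an estimated correlation), which was -0.039 without pre-symptomatic replicate 2. At onset MHC class II had a median of 0.53 (camera adjusted p = 0.0318; adjusted p = 0.974 with an estimated correlation), which was -0.432 without pre-symptomatic replicate 1, and Schwann cell markers had medians of -1.41 at onset and -1.39 in early symptoms. Without pre-symptomatic replicate 1 the early-symptom count was 14, and without replicate 3 it was 2. At onset it was 1 without pre-symptomatic replicate 1 and 1 without onset replicate 3.

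MP at end stage were also set against the 4 age-matched libraries described as WT, to ask for an effect of mutant SOD1 at a given age. Their title, source and strain say G93A, so the contrast is between genotypes only if the description is right. In limma 0 of 10260 genes passed, with 662 at unadjusted p under 0.05. Cd48, an immunoglobulin-family receptor gene of leukocytes (-1.60 ± 0.29, adjusted p = 0.116), Il1r2 (1.38, adjusted p = 0.116), the RNA sensor gene Dhx58 (-2.02, adjusted p = 0.151) and Irf7 (-1.53 ± 0.35, adjusted p = 0.308), at 37.1 ± 21.2 against 101 ± 29.9 FPKM (SD, n = 4 each), did not pass. Adjusted over the list alone 13 of 21 interferon genes were lower in the end-stage group (median -1.18, camera adjusted p = 1.27e-15; adjusted p = 0.195 with an estimated correlation). MHC class II had a median of -0.89 (camera adjusted p = 0.00973; adjusted p = 0.782 with an estimated correlation) and Schwann cell markers -0.89 (camera adjusted p = 0.217).

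Whether the change from pre-symptomatic to end stage differs between nerve macrophages and microglia was tested directly, as an interaction over all 51 non-grafted libraries. The fit treats MG and MP libraries as independent, and whether any of them came from the same mice was not checked. In 2329 of 11773 genes the MP change differed from the MG change, 1120 with a higher and 1209 with a lower value in MP. Spp1 differed by -7.91 ± 1.52 (adjusted p = 0.000922), Ms4a7 by -7.31 ± 1.15, Lpl by -6.79, Lgals3 by -6.33, Cst7 by -6.08, Igf1 by -5.58 ± 0.83 (adjusted p = 0.000107) and Apoe by -3.19 ± 0.90 (adjusted p = 0.0131). Interferon response genes differed too, with Ifi27l2a at -5.75, Ifit3 at -3.42 and Irf7 at -2.73. P2ry12 (-1.34, adjusted p = 0.552), Tmem119 (1.21) and Trem2 (-2.88, adjusted p = 0.12) did not pass. Of the disease-associated genes 20 of 25 had a change lower in MP than in MG (22 adjusted over the list alone; median -3.43, camera adjusted p = 7.41e-14; adjusted p = 0.234 with an estimated correlation). So had 17 of 21 interferon genes (median -2.73, camera adjusted p = 7.37e-12; adjusted p = 0.234 with an estimated correlation). Oxidative phosphorylation (median 0.95, 11 genes higher; adjusted p = 0.297 with an estimated correlation) and the astrocyte markers (median 3.73, 6 genes higher; adjusted p = 0.287 with an estimated correlation) went the other way, and Slc1a2, which fell in MG, differed by 4.63. The oxidative phosphorylation median turned to -0.111 with terms for marker scores. The median of all genes in this contrast was -0.18, and 0.20 after median-ratio scaling, with a split of 1640 higher and 839 lower. With terms for each library's oligodendrocyte, Schwann cell and neutrophil scores 8 genes passed, and with a term for the MP library numbers, which follow stage, 936 passed, 668 of them among the 2329. The count was 1471 without MG pre-symptomatic replicate 2 and 1399 without MG end-stage replicate 1.

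**Figure D2:**
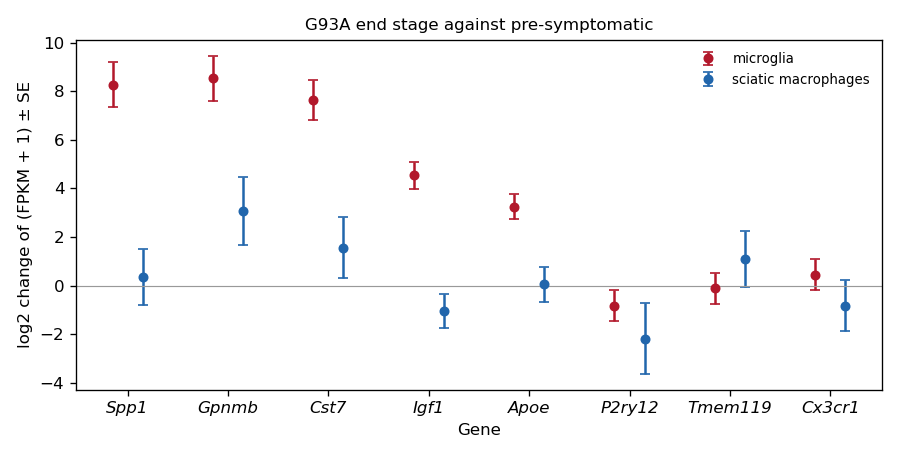
Change from the pre-symptomatic to the end stage in G93A mice, in log2(FPKM + 1) ± SE, for 8 genes in microglia (red) and sciatic nerve macrophages (blue). Spp1 is at 8.27 ± 0.92 in microglia and 0.36 ± 1.16 in macrophages, and Apoe at 3.25 ± 0.52 and 0.06 ± 0.72.

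Bone marrow grafts asked whether replacing peripheral myeloid cells by WT cells changes the microglia or the nerve macrophages of G93A mice. In grafted MG in early symptoms (n = 3 per donor) 0 of 11143 genes differed in limma, with 1229 at unadjusted p under 0.05. Spp1 (-1.41 ± 0.63 for WT minus G93A donor, adjusted p = 0.438) and Apoe (-0.33, adjusted p = 0.846), at 26000 ± 10800 against 31900 ± 11400 FPKM (SD, n = 3 each), did not pass. The genes with the smallest p included Htra1 (3.17) and Gpm6a (3.07), which astrocytes and neurons express, and Itm2a (2.42, adjusted p = 0.407), none of them passing. All 9 astrocyte markers were higher with WT marrow when adjusted over the list alone (median 2.70, camera adjusted p = 1.63e-08; adjusted p = 0.444 with an estimated correlation). So were 7 oligodendrocyte markers (median 1.69; adjusted p = 0.444 with an estimated correlation). The disease-associated list had a median of -0.80 (camera adjusted p = 3.67e-07; adjusted p = 0.447 with an estimated correlation) and the homeostatic list -0.62 (camera adjusted p = 0.000213; adjusted p = 0.475 with an estimated correlation). With terms for oligodendrocyte and neutrophil scores these medians were 0.020 and 0.246. Mbp was at 21258 FPKM in the early-symptom WT-donor replicate 3 and at 951 and 5325 FPKM in the other 2, against 446 to 1786 FPKM with the G93A donor. The early-symptom MG libraries also differed in content by donor. Mitochondrial genes held 2.69% to 6.54% of FPKM with the WT donor and 1.55% to 1.77% with the G93A donor. Features without a symbol held 15.15% to 17.62% against 12.68% to 13.57%. Without WT-donor replicate 1 the early count was 1256 and the count over both stages 581.

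At end stage 0 genes differed between donors in grafted MG in limma, with 53 at unadjusted p under 0.05. Spp1 (0.55 ± 0.63, adjusted p = 1), P2ry12 (0.18) and Apoe (-0.20), at 35200 ± 2360 against 40800 ± 7480 FPKM (SD, n = 3 each), did not pass, and the disease-associated list had a median of 0.00 and a mean of -0.03. The oligodendrocyte list was at 0.79 (camera adjusted p = 0.000205; adjusted p = 0.965 with an estimated correlation). Over both stages 0 genes passed, with 733 at unadjusted p under 0.05, and the disease-associated list had a median of -0.45 (camera adjusted p = 4.57e-05; adjusted p = 0.555 with an estimated correlation), which turned to 0.160 with terms for oligodendrocyte and neutrophil scores. The astrocyte list had a median of 1.62 over both stages, with 9 genes higher adjusted over the list alone (camera adjusted p = 1.69e-08; adjusted p = 0.526 with an estimated correlation). The interaction of donor and stage had 0 genes in limma (191 at unadjusted p under 0.05).

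In grafted MP 0 of 10299 genes differed between donors in limma in early symptoms (n = 2 WT and 3 G93A donor, 245 at unadjusted p under 0.05), at end stage (n = 3 each, 1588) and over both stages (703). The early-symptom genes with the smallest p included Cxcl10, an interferon-induced chemokine gene (-2.41), and at end stage they were Tln1, which links integrins to actin (-2.06 ± 0.36), Prex1 (-2.14), Mast3 (-3.42), Gpn2 (-3.32) and Ppp6r1 (-2.23), all at adjusted p = 0.151. Spp1 had a change of -0.89 ± 2.30 in early symptoms and 0.94 ± 2.05 at end stage, and did not pass at either. Neutrophil markers had a median of 0.90 in early symptoms (camera adjusted p = 9.65e-05; adjusted p = 0.752 with an estimated correlation). MHC class II had a median of -1.10 in early symptoms (camera adjusted p = 0.00894; adjusted p = 0.851 with an estimated correlation), which was 0.078 without G93A-donor replicate 1. At end stage its median was 1.12 (camera adjusted p = 0.0214; adjusted p = 0.792 with an estimated correlation), and -0.092 with terms for Schwann cell and neutrophil scores. The Schwann cell list was at 1.22 at end stage (camera adjusted p = 0.0192; adjusted p = 0.792 with an estimated correlation). Without WT-donor end-stage replicate 2 the end-stage count was 278, and without early-symptom WT-donor replicate 2 the early count was 2 and that over both stages 2. The end-stage libraries also differed in content by donor. Mitochondrial genes held 8.84%, 4.94% and 2.84% of FPKM with the WT donor and 0.96%, 0.33% and 0.35% with the G93A donor, and features without a symbol 16.69% to 23.34% against 10.33% to 12.9%. The interaction of donor and stage had 0 genes in limma (912 at unadjusted p under 0.05).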

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

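The tests of explanations for the disease-associated list in microglia, the terms for cell marker scores, the removal of libraries with S100a8 above 10000 FPKM and the choice of Oaz1 were made only after the results were seen.

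The disease-associated list was higher in end-stage G93A than in WT microglia of the same age, with a median change of 1.95, and had adjusted p = 0.12 with an estimated correlation. A larger share of microglial RNA would raise homeostatic genes as well, yet the disease-associated minus homeostatic score differed by 3.09 with no overlap between mice. Without the libraries with much S100a8 the median was 2.32 (SE of the list score difference 0.73). That of the monocyte markers was -0.84 (SE of the list score difference 0.49). The removal took out WT replicates 1 and 2 and end-stage replicate 4. WT replicates 3 and 4, which stayed, scored -1.626 and -1.1, against -0.758 and -0.791 in WT replicates 1 and 2. The removal can therefore widen the contrast by itself and cannot decide on admixed neutrophils. With or without those libraries no monocyte marker was called higher, which argues against monocytes that keep their markers. Recruited or border macrophages stay open, since their markers went both ways (median -0.07 over all libraries), and without those libraries Ms4a7 was higher by 4.89 (adjusted p = 0.00323) and Cd38 lower by 3.29 (adjusted p = 0.0413). A change in the state of microglia is a candidate explanation that also stays open, and a difference in handling day, which the labels do not give, was not tested.

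In grafted MG of early symptoms the astrocyte markers had a median of 2.70 for WT minus G93A donor, with adjusted p = 0.444 with an estimated correlation and 0 of 11143 genes called in limma, 1229 at unadjusted p under 0.05. If 1 library with much neural RNA, WT-donor replicate 3, were the whole source, the change would vanish without it. The median was then 1.71 (SE of the list score difference 0.79), and 0.84 with terms for oligodendrocyte and neutrophil scores. Uneven carry-over of neural RNA and an effect of the donor therefore both stay open, and these values from 3 mice per donor do not part them. The most abundant myelin gene, Mbp, reached 21258 FPKM in that library.

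In MP the interferon list had a median of -1.18 at end stage against the group described as WT, with adjusted p = 0.195 with an estimated correlation. In limma 0 genes were called over all genes tested, with 662 at unadjusted p under 0.05. With a term for libraries numbered 100 and above the median was -1.63 (SE of the list score difference 0.48). All end-stage libraries are numbered below 100, as is only replicate 1 of the group described as WT. That term therefore rests on single libraries of this group and of the onset group, and cannot decide whether the numbering is the source. With terms for Schwann cell and neutrophil scores the median was -1.04 (SE of the list score difference 0.38). Such terms remove those cells only as far as the scores measure them, so a part played by them stays open. The group's labels disagree on its genotype, so a mutant SOD1 effect, a mislabelled group and a difference in handling stay open. The numbering stays open too. No biological explanation was tested for this list.

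The change from pre-symptomatic to end stage differed between MP and MG in 2329 genes, which include Spp1, Igf1 and Apoe. With terms for marker scores 8 genes passed, and 936 with a term for the MP library numbers, which follow stage. The difference between G93A and WT microglia itself differed between end stage and onset in 1 gene, Oaz1, with 820 at unadjusted p under 0.05. Its row is shared with a pseudogene, Oaz1-ps, and the change was -0.90 ± 0.14 (adjusted p = 0.00457). Of 2791 features without a symbol, which no comparison of the report used, 4.23% were higher in end-stage G93A than in WT microglia in limma, and 270 differed in either direction.

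Single libraries stood apart from the rest of their group in 38 of the 373 gene and group pairs tested, in 13 libraries, by Dixon's test at its 95% limit. Chance passes that limit in about 1 in 20 independent groups, and genes of 1 library that move together are not independent. End-stage G93A microglia replicate 4 was the lowest of its group for Cx3cr1 (166 FPKM), Apoe (12500), Trem2 (578), Itgax (25.3), Lpl (328), Cd68 (546), Colec12 (28.5), Cst7 (395) and Ctsb (1410). WT microglia replicate 3 at the age of end stage was the lowest for Clec7a (18.2 FPKM), Itgax (1.24), Spp1 (82.7), Igf1 (0.06), Cd68 (191), Gpnmb (1.66), Cst7 (11.2), Ms4a7 (0.96) and Mmp12 (5.76), and replicate 1 the highest for Hgf (1.51). WT microglia replicate 4 at the age of onset was the lowest for Clec7a (5.14 FPKM), Cybb (1.13), Cst7 (3.89), Lgals3 (4.69), Ccl4 (13.5), Mnt (1.05) and Ufl1 (11.5). Pre-symptomatic microglia replicate 2 was the lowest for Cybb (0.47 FPKM), Ccl4 (7.95) and Ccl2 (0.3). In early-symptom microglia, replicate 3 was the highest for Gpnmb (764 FPKM) and replicate 2 the lowest for Mobp (332), and B6 replicate 2 at the age of onset was the lowest for Igf1 (0.02). In MP, early-symptom replicate 2 was the highest for Irf7 (105 FPKM). At end stage replicate 3 was the highest for P2ry12 (24.4 FPKM, the others at 0), replicate 1 for Ccl2 (0.01, the others at 0), replicate 2 for Slc1a2 (2.22, the others at 0) and replicate 4 for Il1r2 (780), and replicate 4 was the lowest for Ifit3 (1.03).

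Other splits of the same libraries were counted for each comparison with at least 3 libraries per group, so not for grafted MP in early symptoms or over both stages, where 1 group has 2. For end-stage G93A against WT microglia only the real split of 35 gave as many genes (1 of 35, 822 genes, highest other 71). This is the smallest share that 35 splits can give, and several comparisons were treated this way. A chance split is therefore unlikely but not excluded. The same holds for early symptoms (1 of 35, 4137 genes, highest other 0) and end stage (1 of 35, 6571 genes, highest other 2498) against the pre-symptomatic group. For the difference between MP and MG only a sample of the splits was run. There the real one alone gave as many (1 of 100, 2329 genes, highest other 1787). For onset against WT, 15 of 100 splits gave as many as the real 506 genes, and for onset against pre-symptomatic 13 of 100 gave as many as 2982. The real groups do not stand out from chance in either. The highest other splits called 7641 and 8715 genes, which points to a structure among the onset libraries that the groups do not carry. For MP at end stage against pre-symptomatic the real groups do not stand out from chance either (5 of 35, 1 gene, highest other 2). Where the real count was 0, every split gives as many by construction, so these counts say nothing on chance. This holds for WT against B6 at the age of onset (35 of 35, highest other 0) and of end stage (35 of 35, highest other 3388), MP in early symptoms (35 of 35, highest other 1), MP at end stage against the group described as WT (35 of 35, highest other 2) and grafted MG over both stages (100 of 100, highest other 0). The split with 3388 genes again points to a structure among those libraries. For MP at onset, grafted MG in early symptoms and at end stage and grafted MP at end stage the 10 splits are too few for a share under 0.05. There the real counts were 0 and the highest other counts 0, 0, 1 and 0.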

How the results depend on the processing

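The terms for cell marker scores, the removal of microglia libraries with S100a8 above 10000 FPKM and the term for MP library numbers in the difference between MP and MG were chosen after seeing the data. Most directions of genes and lists that had passed in the report were kept. A result was counted as reversed only if it had passed, while the totals below also hold results that had not. Turns of direction among the latter were not counted. Of 666 results for genes and lists 0 reversed with median-ratio scaling (23 lost and 4 gained the threshold), and 0 of 667 with a pseudocount of 0.1, no filter or the replicate number as a block. With terms for marker scores 20 of 623 reversed and 104 lost the threshold. Where a value below moved or reversed, the cause was not tested. Library quality weights did not converge for the grafted MG fit, where 1 library had a weight of 354, nor for the fit of both cell types. They ran from 0.0643 to 11.5 in non-grafted MG, so libraries entered those counts very unequally. Same-numbered replicates were not correlated above 0.1 throughout in any pairwise comparison, all of them within MG or within MP, so numbers do not pair libraries there. Pairing between MG and MP libraries was not checked. Counts for comparisons not named under a setting stayed within 1.5 times the value in the report.

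With a pseudocount of 0.1, 1159 genes were called at onset against WT, 1 for MP at onset and 1533 for the difference between MP and MG. With no filter the counts were 36 at onset against WT, 9 at onset against pre-symptomatic, 3 for WT against B6 at each age, 3 for MP at onset, 3 in early symptoms, 5 at end stage against pre-symptomatic and 1 against the group described as WT. With median-ratio scaling they were 33 at onset against WT and 2 for MP at end stage against pre-symptomatic, and the median of all genes moved from 0.14 to 0.03 at onset against pre-symptomatic and from 0.09 to -0.04 for WT against B6 at the age of onset. With only the groups compared they were 0 at onset against WT, 379 at end stage against WT, 0 at onset against pre-symptomatic, 2 for WT against B6 at the age of onset and 0 for MP at end stage against pre-symptomatic. With the replicate block they were 4 at onset against WT, 0 at onset against pre-symptomatic and 0 for MP at end stage against pre-symptomatic, where Il1r2 had an adjusted p of 0.0544 (0.86 with only the groups compared and 0.535 with the term for library numbers). With B6 in place of WT controls 6477 genes were called at onset and 5432 at end stage, of which 494 and 749 were also called against WT.

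With library quality weights the counts were 7935 at onset against WT, 5714 at end stage against WT, 8934 at onset and 8357 in early symptoms against pre-symptomatic, 4242 and 8820 for WT against B6 at the ages of onset and end stage, 3 for MP at end stage against the group described as WT, 4978 for grafted MG in early symptoms and 1778 over both stages. The cell cycle list at end stage against WT reversed to -0.37, and the neutrophil list of grafted MG over both stages to 0.985. With the term for library numbers 0 genes were called for MP at end stage against pre-symptomatic and 936 for the difference between MP and MG. Pre-symptomatic and end-stage MP libraries do not overlap in number, so that term rests on other groups. Under it MHC class II at onset (-0.56), the disease-associated list in early symptoms (-0.052) and the same list against the group described as WT (-0.10) reversed.

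With terms for marker scores the counts were 6 at onset against WT, 2209 at end stage against WT (777 of the 822 genes shared), 1 at onset, 2478 in early symptoms and 2269 at end stage against pre-symptomatic (6 of the 1741 shared genes in the opposite direction), 2 and 1 for WT against B6 at the ages of onset and end stage, and 8 for the difference between MP and MG. In microglia the oligodendrocyte score itself was 7.088 to 7.483 before symptoms and 4.383 to 6.415 at end stage, so these terms also take up effects of stage, and the lower counts do not part composition from disease. Under these terms Gpnmb (5.23), Apoe (2.21) and P2ry12 (-2.82) kept their direction at end stage against WT. Reversed at onset against WT were the lysosome (-0.22), inflammatory (-0.15), MHC class I (-0.25) and complement (-0.47) lists, and at end stage MHC class I (-0.021). At onset against pre-symptomatic Sod1 (0.011), Hmgcs1 (0.061), MHC class II (-0.12) and complement (-0.02) reversed. MHC class II reversed for MP at end stage against pre-symptomatic (0.12), in the difference between MP and MG (0.14) and in grafted MP at end stage (-0.092), and oxidative phosphorylation in the difference (-0.11). In grafted MG of early symptoms the homeostatic (0.25), disease-associated (0.02) and interferon (0.22) lists reversed, and over both stages the homeostatic (0.21), disease-associated (0.16), lysosome (0.14) and neuronal (-0.10) lists. Without libraries of S100a8 above 10000 FPKM the counts were 18 at onset and 1669 at end stage against WT (677 shared), and 44 at onset against pre-symptomatic.

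Leaving out 1 library at a time gave 2 to 4978 genes at onset and 357 to 1117 at end stage against WT, and 0 to 6968, 1534 to 4500 and 5326 to 6766 at onset, in early symptoms and at end stage against pre-symptomatic. It gave 0 to 0 and 0 to 10 for WT against B6 at the ages of onset and end stage. For MP it gave 0 to 1 at onset, 0 to 14 in early symptoms, 0 to 61 at end stage and 0 to 0 against the group described as WT, and for the difference between MP and MG 1399 to 2529. For grafted MG it gave 0 to 1256 in early symptoms, 0 to 0 at end stage and 0 to 581 over both stages, and for grafted MP 0 to 2, 0 to 278 and 0 to 2. Where 1 library was left in grafted MP with WT marrow in early symptoms, it was assumed to vary like the other groups. Lists that reversed when 1 library was left out are given with their lowest and highest medians. At end stage against WT these were the cell cycle list (-0.056 without WT replicate 3, 0.704 highest) and the antioxidant list (-0.083 without WT replicate 3, -0.009 without G93A replicate 4, 0.354 highest). In MP they were MHC class II at onset (-0.432 without pre-symptomatic replicate 1, 1.232 highest) and the neutrophil list in early symptoms (-0.039 without pre-symptomatic replicate 2, 0.583 highest). In grafted MG they were the interferon list in early symptoms (0.007 without WT-donor replicate 3, -0.861 lowest) and the neutrophil list over both stages (0.067 without early G93A-donor replicate 3, -1.449 lowest). In grafted MP they were MHC class II in early symptoms (0.078 without G93A-donor replicate 1, -2.095 lowest) and the Schwann cell list over both stages (-0.049 without early G93A-donor replicate 3, 0.61 highest).

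Read depth is unknown, so a gene at 0 FPKM is not shown to be absent. Values near 1 FPKM carry 2 decimals only, and their changes are understated on the log2(FPKM + 1) scale. At these group sizes the simulated MP data gave 27 of 100 calls for changes of 2 log2 units, so counts of 0 in MP leave room for changes of that size.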

Other observations

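Some trophic and antioxidant genes of microglia were called beside the lists above. Against WT at end stage Hgf, which encodes hepatocyte growth factor, rose by 0.99 (adjusted p = 0.031) and Txnrd1, which encodes thioredoxin reductase, by 0.60 (adjusted p = 0.0077). Of 10 trophic factor genes 2 were higher, or 3 higher and 1 lower adjusted over the list alone (median 0.48, camera adjusted p = 0.00255; adjusted p = 0.11 with an estimated correlation). Of 14 antioxidant genes 2 were higher, or 3 adjusted over the list alone (median 0.08, camera adjusted p = 0.0183; adjusted p = 0.114 with an estimated correlation). The antioxidant median rested on single libraries, at -0.083 without WT replicate 3, -0.009 without G93A replicate 4 and 0.354 at the highest. From pre-symptomatic to end stage 7 of 8 NADPH oxidase genes rose (median 2.68, camera adjusted p = 0.00176; adjusted p = 0.324 with an estimated correlation). In the same contrast the cytokine genes Osm and Tgfb1 rose by 2.74 and 2.48, and Vegfa, a vascular growth factor gene, fell by 2.34. Stage and age rise together there, and against WT of the same age the NADPH oxidase list had a median of 0.40 with 0 genes called in limma (camera adjusted p = 0.104).

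In nerve macrophages the alternative activation list, which holds Mgl2, had a median of -2.13 from pre-symptomatic to end stage, with 0 of 13 genes called over all genes. Adjusted over the list alone 4 were lower and 1 higher (camera adjusted p = 0.000542; adjusted p = 0.506 with an estimated correlation). Against the group described as WT, whose other labels say G93A, the median was -0.99 (camera adjusted p = 0.0294; adjusted p = 0.782 with an estimated correlation).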
